A study of Caenorhabditis elegans with 12 samples.

How the data were processed

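The data were RNA sequencing counts from 12 whole-body libraries of Caenorhabditis elegans, harvested as day 0 adults. Wild-type N2 animals and animals with the isp-1(qm150) mutation were fed control bacteria or bacteria expressing double-stranded RNA against vrk-1, on plates with 10 mM IPTG. The 4 groups held 3 libraries each, numbered 1 to 3 in the titles. The labels do not state whether replicates were separate cultures. Per the labels, libraries were poly(A)-selected and stranded (TruSeq Stranded mRNA). The submitters' processing notes name HISAT2 2.0.5 and the WBcel235 genome build, also called ce11. The counting tool, the annotation release and the use of strand were not given in the sources used here.

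Each deposited table holds unnormalised counts per gene, tested on the files as whole numbers. Each held 44107 lines, of which 1 repeated a gene identifier and was summed, leaving 44106 genes. Identifiers were looked up in the WBcel235 annotation, where 44020 matched and 86 did not, and 43023 had a symbol. A further 2906 annotated genes, 554 of them protein-coding, were not analysed here. The sum of counts per library ranged from 17567955 to 22824619, which sets the precision of low values. Folds against a group with no counts are lower bounds against a floor of 3 counts over the group's 3 libraries, and they cover counting error only. The floor was scaled by total counts and the level with TMM (below). Wild-type TMM factors were 0.92 to 0.98, so folds against a wild-type floor run slightly high and are approximate. Genes in near-identical families (vitellogenins, major sperm proteins, collagens, hsp-16, fbxb and pud genes) can share reads, so values of single members are less certain than those of their group.

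Counts were scaled with TMM and filtered with filterByExpr (minimum count 10, minimum total 15) in edgeR 4.0.16 under R 4.3.3, which left 14856 genes. A quasi-likelihood model with robust dispersion and 1 mean per group was fitted to all 12 libraries, with 8 residual degrees of freedom. The common biological coefficient of variation was 13.5%. Log2 fold changes are given with standard errors, from 3 libraries per group, and levels as CPM (counts scaled by library size, as in edgeR) with standard deviations. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The contrasts were vrk-1 RNAi against control RNAi in wild type and in isp-1, isp-1 against wild type on each bacteria, and the interaction, which is the vrk-1 RNAi effect in isp-1 minus that in wild type.

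The contrasts, the rule for named genes, 33 gene lists and most alternatives were fixed before the data were examined. Named genes were vrk-1, isp-1 and aak-2. To these the rule added the 10 higher and 10 lower called genes with the largest fold change (5 and 5 for isp-1 on vrk-1 RNAi and for the interaction), with a mean of at least 5 CPM. Their groups did not overlap, except for the interaction, where overlap was not examined. It also added up to 4 called members per list with the smallest adjusted p, and the 5 largest mean changes for genes called in both of 2 contrasts. Mitochondrially encoded genes were taken by chromosome, since their list names were not in the annotation.

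Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the 33 lists within a contrast. With the correlation estimated for each list, 0 of the 33 lists were called in any of the 5 contrasts. The smallest adjusted p was then 0.832 for vrk-1 RNAi in wild type, 0.0734 for vrk-1 RNAi in isp-1, 0.0561 for isp-1 on control RNAi, 0.0711 for isp-1 on vrk-1 RNAi and 0.0501 for the interaction. Fry, which tests whether the members of a list move in 1 direction on balance, called 0, 7, 22, 18 and 1 lists in the same order. Counts of members are over all genes tested, and those "adjusted over the list alone" are marked as such.

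Whether the replicate numbers pair the libraries was checked across genes from each library's deviation from its group mean. In wild type, libraries of the same number in both RNAi groups correlated at 0.15, 0.299 and 0.224, and in isp-1 at 0.304, 0.542 and 0.346, whereas differently numbered pairs within the genotypes ranged from -0.374 to 0.034. Between the genotypes the same-numbered pairs ranged from -0.175 to 0.284 and the differently numbered pairs from -0.268 to 0.327. Results with the replicate number as a block are therefore given beside the counts for vrk-1 RNAi and the interaction where they changed a call or moved a count by over 1.5 times, and those with the block within each genotype where they changed the call of a list.

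Alternatives were DESeq2 size factors, total counts without further scaling, no count filter, DESeq2 1.42.0 with its Wald test, a replicate block, a 2-fold minimum, the 6 compared libraries alone, and leaving out each library. DESeq2 gave no adjusted p for 871 genes in the wild-type vrk-1 RNAi contrast, 1447 in the interaction and 6 in each other contrast. Such genes were kept as not called. A block within each genotype, leaving out both vrk-1 RNAi replicate 2 libraries, and leaving out the vitellogenin genes were added after the data were seen, the last before its own result was. As coded, the block within each genotype makes the isp-1 against wild type contrasts compare the fitted levels of replicate 1, not group means. The vrk-1 RNAi contrasts and the interaction are not affected by this. The scalings moved the median log2 fold change of all genes: total counts in place of TMM moved it by 0.195 for isp-1 on control RNAi, by 0.113 for isp-1 on vrk-1 RNAi and by less than 0.1 in the other contrasts.

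The procedure was tested on simulated data with 200 changed genes. A 2-fold change was called for 46.3% of the changed genes for the interaction and for 61.2% to 77.6% in the other contrasts, and a 4-fold change for 77.3% to 95.5%. A 1.5-fold change was called for 9% to 44.8%. These rates are those of edgeR. Calls on unchanged genes numbered 4 to 11 per contrast by edgeR and 14 to 24 by DESeq2. For the interaction they were 7 of 99 calls by edgeR and 18 of 123 by DESeq2. All 4 shifted lists and 0 of 16 unshifted lists were called in each contrast. Genes were simulated as independent. The simulation therefore cannot show how often camera at the preset correlation calls unchanged lists whose members vary together.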

Results

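Gene expression was measured by RNA sequencing in whole C. elegans at day 0 of adulthood, in wild-type (N2) animals and in isp-1(qm150) mutants, each fed control RNAi or vrk-1 RNAi bacteria. ISP-1 is the Rieske iron-sulfur protein of mitochondrial complex III, and the qm150 allele lowers respiration and lengthens life. VRK-1 is a nuclear serine/threonine kinase that acts on the nuclear envelope in dividing cells. The series title links VRK-1 to AMP-activated protein kinase (AMPK) and lifespan. The 4 groups held 3 libraries each, with 17567955 to 22824619 counts per library. The 1st principal component held 61.9% of the variance of log2 CPM and parted the genotypes, and the 2nd held 18.1%.

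The level of the targeted transcript was examined before the comparisons. In wild type, vrk-1 (WBGene00017895, II:5921967-5924838 in WBcel235) stood at 114.2 ± 2.1 CPM on control RNAi (SD, n = 3). On vrk-1 RNAi, replicates 1 and 3 had 43.2 and 43.3 CPM, 37.8% and 37.9% of the control mean, while the library labelled vrk-1 RNAi replicate 2 had 112.3 CPM, 98.4% of it. In isp-1, the control level was 95.3 ± 8.7 CPM. There, vrk-1 RNAi replicates 1 and 3 had 56.7 and 40.2 CPM (59.5% and 42.1%), and the library labelled replicate 2 had 88.4 CPM, 92.8% of the control mean. Over all 3 libraries per group, a two-sided exact permutation test gave p = 0.1 in wild type, the smallest that 3 against 3 libraries allow, and p = 0.2 in isp-1. In the edgeR model the log2 change of vrk-1 was -0.79 ± 0.40 in wild type (adjusted p = 1) and -0.62 ± 0.40 in isp-1 (adjusted p = 0.304). Without vrk-1 RNAi replicate 2 of the same genotype, vrk-1 was called in wild type (-1.40 ± 0.26, adjusted p = 0.032) and had -0.97 in isp-1 (adjusted p = 0.125). Replicate 2 was singled out here by its vrk-1 level, so these values are no separate evidence of a knockdown. Leaving out isp-1 vrk-1 RNAi replicate 3 gave -0.39 there (adjusted p = 0.588). Part of the transcript can also come from the double-stranded RNA itself, which these counts do not separate.

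**Figure D1:**
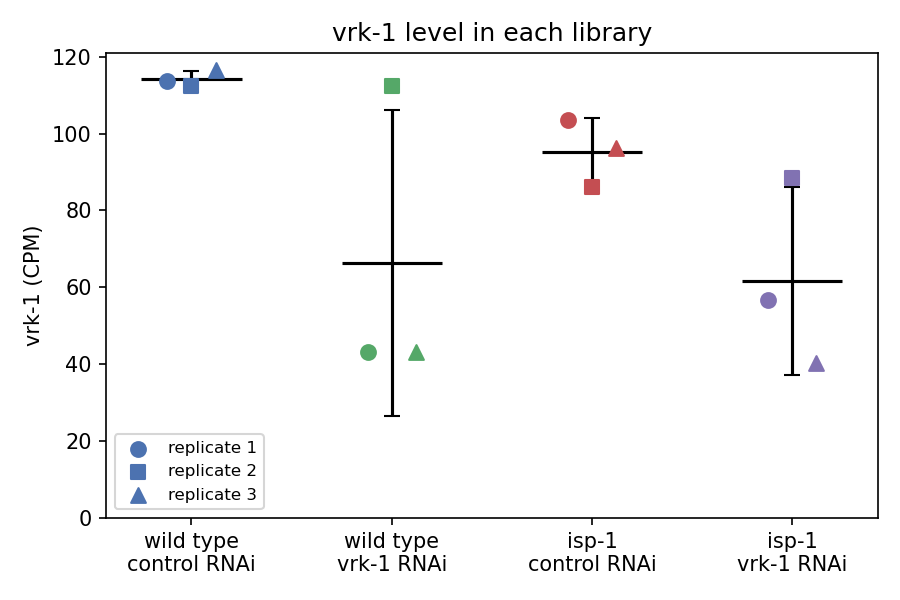
Level of vrk-1 (CPM, linear axis from 0) in each of the 12 libraries, with group means (horizontal lines) and standard deviations (bars, n = 3); circles, squares and triangles are replicates 1, 2 and 3. The libraries labelled vrk-1 RNAi replicate 2 sit at 112.3 CPM in wild type and 88.4 CPM in isp-1, near their controls.

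The effect of vrk-1 RNAi in wild type compares animals with intact respiration on vrk-1 RNAi and on control RNAi. No gene was called by edgeR, with 504 of 14856 genes at an unadjusted p under 0.05 where chance gives 743, and DESeq2 called 0 higher and 6 lower. The smallest adjusted p was 0.061, for folt-2, a folate transporter family gene named after its values were seen, with a log2 change of -0.79. AMPK catalytic subunit gene aak-2 (WBGene00020142, X:16796087-16803398) had a log2 change of -0.05 ± 0.08 and isp-1 (WBGene00002162, IV:8134016-8136055) -0.09 ± 0.08, both with an adjusted p of 1.

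Among the lists in wild type, 13 of 33 were called by camera at the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.832. With the replicate block the oocyte list was also called (adjusted p = 0.0397, 0.0572 without the block), with 0 of 17 members called. With a block within each genotype, added after the data were seen, 4 lists not called without a block were called: oocyte genes (adjusted p = 0.0162), vitellogenins (0.0129), DAF-16 class I targets (0.0441) and adult cuticle collagens (0.00023), each at 0.832 with an estimated correlation. The lists furthest from 0 were early embryonic zygotic genes (4 of 4 members negative, median log2 change -1.34, for example vet-6 at -1.73 ± 0.83), larval molting genes (15 of 17 negative, median -0.40) and all cuticle collagens (127 of 156 negative, median -0.32). DNA replication and mitosis genes had positive values for 22 of 23 members with a median of 0.07, and the 6 vitellogenins, the yolk proteins, a median of 0.13. These medians rest on single libraries. Without wild-type vrk-1 RNAi replicate 2 they were -4.16 for early embryonic (3 of 4 called lower), -0.71 for molting, -0.75 for collagen, 0.13 for replication and 0.23 for vitellogenin genes. Without vrk-1 RNAi replicate 3 they were -0.83, -0.18, -0.11, 0.02 and 0.03 in the same order. The early embryonic and collagen medians were -0.78 and -0.19 without vrk-1 RNAi replicate 1. Without control replicate 3 the molting and collagen medians were -0.61 and -0.60, and without control replicate 2 the collagen median was -0.01. The count of 0 rested on the library at control vrk-1 level: without wild-type vrk-1 RNAi replicate 2, 20 genes were higher and 165 lower. They included the early embryonic genes vet-6 (-4.19 ± 0.41) and sdz-28 (-4.13 ± 0.43), the Skp1-related gene skr-8 (-3.70 ± 0.38), the cystathionine gamma-lyase gene cth-1 (-1.77 ± 0.15) and the heme transporter gene hrg-1 (-1.66 ± 0.16), named after their values were seen.

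The effect of vrk-1 RNAi in isp-1 compares the long-lived respiratory mutant on vrk-1 RNAi and on control RNAi. A fall of vrk-1 was not called there, and the changes are not shown to follow its level. With vrk-1 at 92.8% of the control mean, isp-1 vrk-1 RNAi replicate 2 had 5.8% of counts in vitellogenins. Replicates 1 and 3 had 8.2% and 7.5%, and the isp-1 controls 2.6% to 3.6%. In wild type, vrk-1 RNAi replicates 1 and 3 had 8.2% and 9.2%, against 7.2% to 7.9% in the controls. The 6 vitellogenins were all called higher, with a median log2 change of 1.98 (camera adjusted p = 4.45e-22; adjusted p = 0.0734 with an estimated correlation): vit-3 rose from 66.2 ± 18.6 to 389.4 ± 123.2 CPM (2.56 ± 0.27), vit-5 from 2270 ± 410.4 to 8598 ± 1838 CPM (1.92 ± 0.17), vit-4 by 2.33 ± 0.27 and vit-1 by 2.05 ± 0.22. Sperm genes were called lower for 17 of 19 members (median -1.18, camera adjusted p = 2.89e-11; adjusted p = 0.573 with an estimated correlation), among them the major sperm protein gene msp-10 (-1.17 ± 0.18) and spe-11 (-1.38 ± 0.23), which encodes a sperm factor needed in the embryo. Larval molting genes fell for 10 of 17 members (median -1.22, camera adjusted p = 1.27e-06; adjusted p = 0.573 with an estimated correlation), such as dpy-7 (-1.32 ± 0.30) and noah-1 (-1.33 ± 0.29). Of 156 cuticle collagens, 37 fell while 4 rose (median -1.26, camera adjusted p = 4.9e-10; adjusted p = 0.699 with an estimated correlation).

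All 6 vitellogenins stayed called whichever isp-1 library was left out, but the other counts fell. Without isp-1 control replicate 2, vrk-1 RNAi replicate 1 or vrk-1 RNAi replicate 3, the sperm genes called lower were 7, 8 and 8, the molting genes 0, 0 and 0 and the collagens 7, 4 and 6, and 4 molting genes were called without control replicate 3. The medians stayed between -1.36 and -0.99 for sperm, -1.50 and -1.02 for molting and -1.54 and -1.02 for collagen genes.

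Adjusted over the list alone, 6 vitellogenins, 18 sperm genes, 15 molting genes and 80 collagens passed in these directions, and 1 sperm gene and 6 collagens in the other. Oocyte and eggshell genes were higher for 6 of 17 members (median 0.39; 12 adjusted over the list alone), such as the vitelline layer genes perm-2 (1.02 ± 0.13) and perm-4 (0.94 ± 0.13). DNA replication and mitosis genes were higher for 9 of 23 (median 0.32; 15 adjusted over the list alone), such as the cyclin B gene cyb-3 (0.69 ± 0.13) and the ribonucleotide reductase gene rnr-2 (0.53 ± 0.11). The nuclear envelope list, which holds the VRK-1 substrate gene baf-1, had 4 of 17 members higher (median 0.23), among them lem-3 (0.39 ± 0.10) and lem-2 (0.31 ± 0.10). Camera called these 3 lists as well (adjusted p = 9.1e-08, 3.31e-07 and 0.002), with adjusted p of 0.573, 0.686 and 0.699 with an estimated correlation. Without isp-1 control replicate 2, vrk-1 RNAi replicate 1 or vrk-1 RNAi replicate 3, the members called higher were 2, 2 and 2 oocyte, 2, 5 and 4 replication and 0, 0 and 0 nuclear envelope genes. Without vrk-1 RNAi replicate 2 they were 17, 17 and 10, and without control replicate 3 the nuclear envelope list had 2. With the replicate block 112 collagens were lower, 11 oocyte and 15 replication genes higher and 1 sperm gene higher. The adult cuticle collagens then had 4 of 5 lower in place of 1 and were called as a list (adjusted p = 0.0418, 0.122 without the block; adjusted p = 0.699 with an estimated correlation). The block within each genotype also called them (adjusted p = 2.52e-06).

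Several stress and metabolic lists also had called members in isp-1. In the AMPK list, 3 of 12 genes were higher: the LKB1 kinase gene par-4 (0.44 ± 0.10), the gamma subunit gene aakg-5 (0.26 ± 0.08) and aak-2 (0.24 ± 0.08, adjusted p = 0.040), and the list itself was not called (adjusted p = 0.11). The aak-2 call was lost with total counts (0.15), with no count filter (0.24), with the 6 libraries alone (0.25) and without isp-1 control replicate 1 (0.22) or 2 (0.25) or isp-1 vrk-1 RNAi replicate 1 or 3 (0.23 each). Glutathione S-transferase genes of the SKN-1 list were higher for 3 of 15 members (gst-4, 0.85 ± 0.14; gst-13, 0.65 ± 0.14; gst-10, 0.60 ± 0.19), and 6 of 20 lipolysis and fatty acid oxidation genes were higher and 1 lower, with ech-6 at 0.45 ± 0.10. The aakg-5 call was lost without isp-1 control replicate 2 or 3 or vrk-1 RNAi replicate 1 or 3, the gst-10 call without any 1 isp-1 library but vrk-1 RNAi replicate 3, and the ech-6 call without vrk-1 RNAi replicate 1. Camera called both lists (adjusted p = 0.0285 and 0.0178; adjusted p = 0.573 for each with an estimated correlation). In the HIF-1 and hypoxia list 4 of 12 members were lower, the sulfide-response gene cysl-2 by the most (-0.90 ± 0.19), and camera did not call it (adjusted p = 0.251). Camera also called DAF-16 class II genes (1 of 5 higher, median 0.49, adjusted p = 0.0269), cytosolic ribosomal genes (2 of 81 lower, median -0.14, adjusted p = 0.00129) and proteasome genes (0 of 33 called, median 0.12, adjusted p = 0.0285), with adjusted p = 0.573, 0.699 and 0.858 with an estimated correlation. Detoxification genes went both ways: cyp-25A1 rose (2.62 ± 0.31) and ugt-16 fell (-1.19 ± 0.21), with 6 higher and 5 lower of 59 cytochrome P450s and 3 higher and 5 lower of 60 UDP-glucuronosyltransferases. These counts also fell without single libraries. Without isp-1 control replicate 2 or vrk-1 RNAi replicate 1, the AMPK list had 1 and 1 higher, the lipolysis list 2 and 1 higher, the HIF-1 list 2 and 1 lower, and the cytochrome P450s and UDP-glucuronosyltransferases 1 lower each, with 3 cytochrome P450s higher. The AMPK list had 1 higher without vrk-1 RNAi replicate 3, which also gave 3 cytochrome P450s lower and 8 UDP-glucuronosyltransferases higher and 2 lower, and the lipolysis list had 3 without control replicate 1 or 3. With the replicate block the SKN-1 list had 5 higher and 1 lower and was not called (adjusted p = 0.0561; 0.103 with the block within each genotype). DAF-16 class II genes then had 2 higher, cytochrome P450s 8 lower, mitochondrial unfolded protein response genes 2 lower in place of 1 and proteasome genes 1 higher. The block also called 1 glycolysis gene higher and 1 lower, 1 autophagy gene and 2 neuron markers lower, and 1 germline gene and 1 neuron marker higher.

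Among called genes with a symbol, a mean of at least 5 CPM and no overlap between the isp-1 groups, the largest changes in each direction were those of F41G4.7 (WBGene00018310), which rose from 5.2 ± 1.5 to 43.5 ± 9.9 CPM (3.06 ± 0.23), and of the collagen gene dpy-14 (WBGene00001075), which fell from 24.7 ± 13.2 to 0.34 ± 0.06 CPM (-6.16 ± 1.46). T22B7.7, H11L12.1, nta-1, R09E10.2 and ZK105.1 also rose, by 2.37, 2.04, 1.54, 1.31 and 1.31. The linker histone gene his-24 fell from 58.8 ± 15.3 to 12.5 ± 1.8 CPM (-2.23 ± 0.53), and clec-266, dpy-17, F59C6.18, C35E7.5, K03D3.2, the chitinase gene cht-1, M70.1 and col-90 fell by values between -3.08 and -1.67. Many of these falls rest on single libraries: dpy-14, dpy-17, F59C6.18, his-24 and col-90 were not called without isp-1 control replicate 2 or vrk-1 RNAi replicate 1 or 3. The same held for clec-266, C35E7.5 and cht-1, which were also not called without control replicate 1 or vrk-1 RNAi replicate 2, and nta-1 was not called without control replicate 2.

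In all, edgeR called 1091 genes higher and 1832 lower for vrk-1 RNAi in isp-1, with 96 and 1355 past a 2-fold change, and DESeq2 called 1316 and 1932. With the replicate number as a block, 1742 were higher and 2567 lower. The counts rested on single libraries: they fell to 316 and 733 without isp-1 control replicate 2 and to 315 and 673 without vrk-1 RNAi replicate 1. The lower genes fell to 983 without vrk-1 RNAi replicate 3, and the higher genes rose to 1910 without vrk-1 RNAi replicate 2. Total-count scaling gave 588 higher, so that 22.3% rather than 37.3% of called genes were higher.

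**Figure D2:**
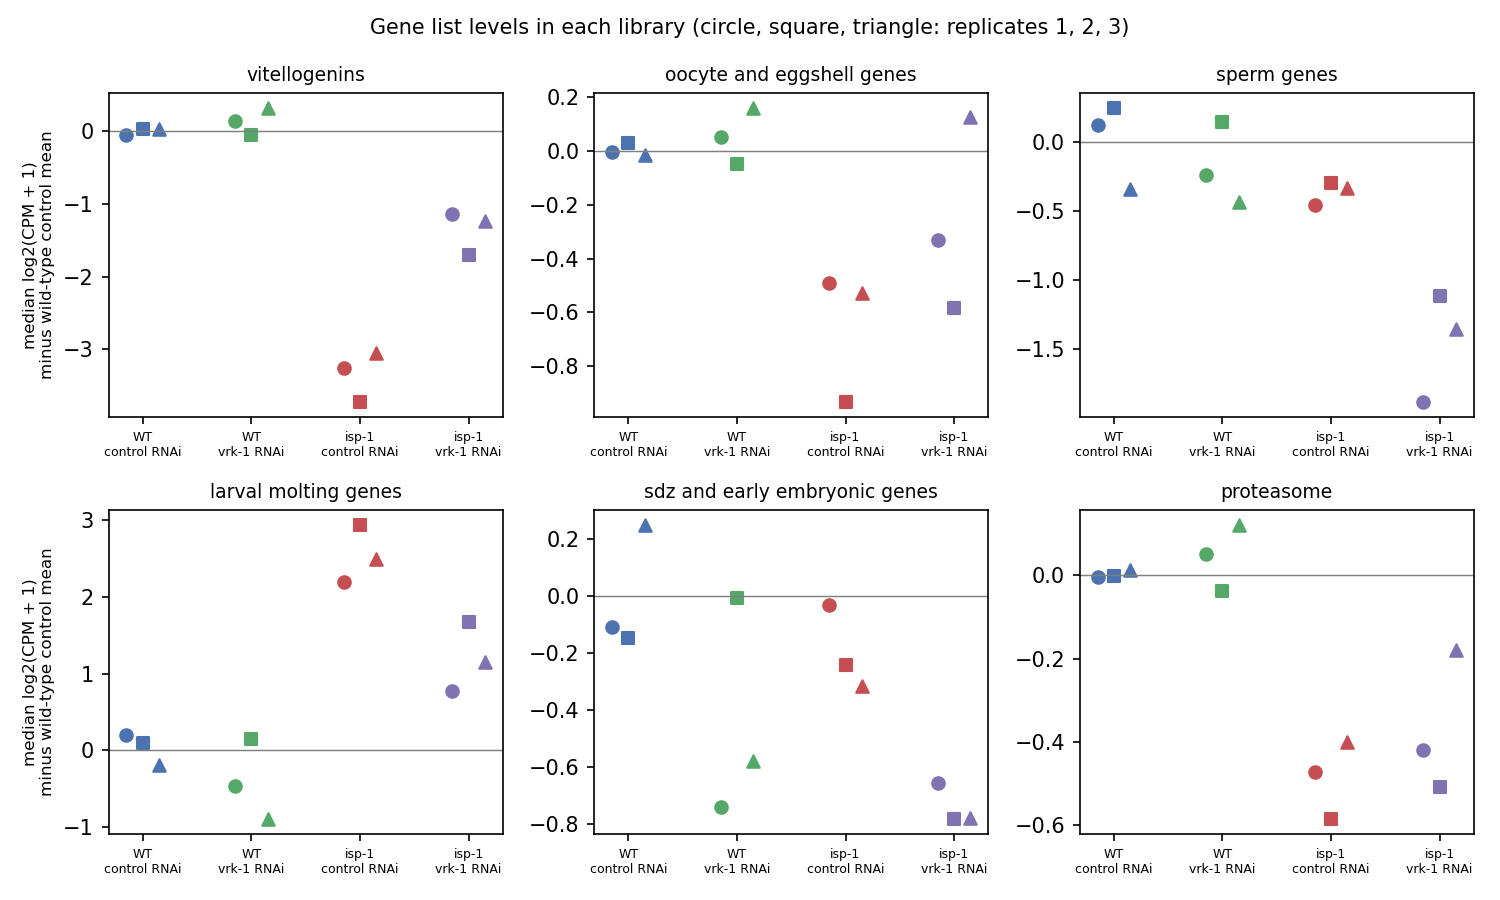
Median over the members of 6 gene groups of log2(CPM + 1) in each library, minus the wild-type control mean of each gene; circles, squares and triangles are replicates 1, 2 and 3, and each panel has its own axis. Vitellogenins sit at -3.73 to -3.05 in isp-1 on control RNAi and at -1.71 to -1.14 on vrk-1 RNAi, and sperm genes at -0.46 to -0.29 and -1.88 to -1.12.

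The comparison of isp-1 with wild type on control RNAi gives the state of the mutant without vrk-1 RNAi. Whole animals were sampled. Differences in developmental timing or tissue proportions at harvest are therefore not separated from other effects of the mutation. Yolk, oocyte and proteasome genes were lower, and most molting, hypoxia-response, DAF-16 class I, neuron marker and collagen genes were higher. All 6 vitellogenins fell (median log2 change -3.32), with vit-3 going from 5181 ± 192.8 to 66.2 ± 18.6 CPM (-6.29 ± 0.31). The stearoyl-CoA desaturase gene fat-7 fell from 63.4 ± 10.9 to 0.16 ± 0.03 CPM (-8.54 ± 0.24), the smallest adjusted p of the contrast (1.35e-11). Of the HIF-1 and hypoxia genes, 8 of 12 rose (median 0.95), including sqrd-1 (3.32 ± 0.21), cysl-2 (3.10 ± 0.20) and the prolyl hydroxylase gene egl-9 (1.06 ± 0.08). The DAF-16 class I targets had 9 higher and 1 lower of 13 (median 1.79), such as the superoxide dismutase gene sod-3 (2.14 ± 0.17) and the isocitrate lyase gene icl-1 (2.15 ± 0.14), while 5 of 5 DAF-16 class II genes were lower (median -1.87), with dod-24 at -5.50 ± 0.88.

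Larval molting genes rose for 16 of 17 members (median 2.59), for example dpy-7 (3.05 ± 0.33) and mlt-11 (2.95 ± 0.37), and 102 of 156 collagens rose and 6 fell (median 2.13, also with genes without counts at their bound). Of the neuron markers 13 of 17 rose (median 0.60), including the proprotein convertase gene egl-3 (0.98 ± 0.11), and of the antioxidant enzymes 7 of 15, with sod-5 at 5.14 ± 0.56. Glycolysis, gluconeogenesis and glyoxylate genes had 11 higher and 4 lower of 21, with the phosphoenolpyruvate carboxykinase gene pck-1 at 2.60 ± 0.12, cytochrome P450s 27 higher and 15 lower of 59, with cyp-14A4 at 4.14 ± 0.20, and autophagy genes 8 higher and 1 lower of 15, with sqst-1 at 1.47 ± 0.09. All 33 proteasome genes fell (median -0.49, for example rpt-4 at -0.62 ± 0.08), as did 65 of 81 cytosolic ribosomal protein genes (median -0.30; 2 rose, with rpl-25.1 at 0.60), all 23 DNA replication and mitosis genes (median -0.55), all 17 oocyte genes (median -0.62), 14 of 20 germline stem cell and meiotic genes (median -0.50) and 14 of 17 nuclear envelope genes (median -0.41; 1 rose, unc-83). Fatty acid synthesis genes had 3 higher and 5 lower of 16. These directions held under total counts except for the fatty acid synthesis median, which turned from -0.07 to 0.12, and the ribosomal median shrank to -0.10.

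Camera called the 18 lists of the preceding paragraphs for isp-1 on control RNAi, with adjusted p between 5.94e-17 for vitellogenins and 0.0498 for autophagy (0.0818 with the replicate block, which ends that call). The block within each genotype, which compares replicate 1 levels here, ended the calls of cytochrome P450s (adjusted p = 0.0526) and fatty acid synthesis genes (0.109). With an estimated correlation the adjusted p was 0.0561 for vitellogenins, HIF-1 genes and DAF-16 class I targets, 0.0983 for DAF-16 class II genes and antioxidant enzymes, 0.153 for fatty acid synthesis and between 0.443 and 0.531 for the others. Adjusted over the list alone the counts differed by at most 6 genes in any of these lists, with 105 collagens higher and 71 ribosomal genes lower. Of these lists, neuron markers had 8 higher and autophagy genes 5 higher without wild-type control replicate 3, autophagy genes 5 higher without isp-1 control replicate 1 and collagens 12 lower without isp-1 control replicate 3.

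The other lists were not called for isp-1 on control RNAi. Only the block within each genotype, which compares replicate 1 levels here, called sperm genes by camera (adjusted p = 6.97e-05, 0.0668 without a block). The mitochondrial unfolded protein response had 5 higher and 2 lower of 12, with gpd-2 at 0.90 ± 0.10; its chaperone hsp-6 was not called (-0.15 ± 0.12) and hsp-60 fell (-0.47 ± 0.11), both named after their values were seen. The nuclear-encoded respiratory chain had 12 higher and 4 lower of 35, with ucr-2.1 at 0.55 ± 0.08, mitochondrially encoded genes 2 higher of 12, and AMPK genes 4 higher and 3 lower of 12, with aakg-4 at 1.11 ± 0.13 and aak-1 at -0.39 ± 0.07. The SKN-1 list had 3 higher and 7 lower of 15, UDP-glucuronosyltransferases 20 and 17 of 60, innate immune effectors 5 and 7 of 18, lipolysis and oxidation genes 3 and 7 of 20, sperm genes 1 and 8 of 19, and the endoplasmic reticulum response 4 and 5 of 15. The cytosolic heat shock list had 3 higher and 4 lower of 11, and its median (1.12) and mean (0.82) were positive while camera's direction was down. The SKN-1 median (-0.13) and mean (0.10) also differed in sign. Intestine markers had 4 higher and 4 lower of 12, body wall muscle markers 1 higher of 14, adult cuticle collagens 2 higher of 5, and early embryonic genes 0 of 4. Some of these counts rest on single libraries. Sperm genes lower were 5 and 4 without wild-type control replicates 1 and 2 and 3 without isp-1 control replicate 2, and respiratory chain genes higher were 7 without isp-1 control replicate 1. Heat shock genes higher were 1 without wild-type control replicate 2 or isp-1 control replicate 1 or 2, and endoplasmic reticulum genes higher were 2 and 1 without wild-type control replicates 1 and 3 and 1 and 2 without isp-1 control replicates 1 and 2. Endoplasmic reticulum genes lower were 2 without wild-type control replicate 1 and 3 without isp-1 control replicate 3.

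Some genes had counts in only 1 genotype. Against the floor for wild-type control libraries without a count, the collagen genes col-36, col-37 and col-84 were 511.1-fold, 437.5-fold and 207.9-fold higher in isp-1. F47H4.2 and lsy-27 were 339.1-fold and 293.5-fold higher against it. The collagen bounds rest on isp-1 control replicate 2: without it they are 211.3-fold, 165.3-fold and 79.5-fold. In isp-1 control replicate 3 the 3 collagen genes had only 1.33, 0.41 and 0.25 CPM. The col-37 call was lost without any 1 library but isp-1 control replicate 3. F47H4.2 and lsy-27 lie in a run of 43 neighbouring genes without a count in any of the 6 wild-type libraries. These counts do not separate a change in expression from a difference in the DNA of the strains there. Conversely, pud-4 and the arginine kinase gene argk-1 were at least 1793-fold and 1206-fold lower in isp-1, argk-1 with 0 counts in all 6 isp-1 libraries. The neighbouring genes pud-3, pud-1.2 and pud-2.2 (WBGene00017490) had 9, 15 and 20 counts in the isp-1 control libraries against 14295, 4010 and 4391 in wild type, and the other pud-2.2 copy (WBGene00017500) and pud-1.1 had 1 and 2 against 1268 and 827. In the other direction col-2 had 1638 counts against 2, and F22B3.7, clec-17, grl-25 and cut-1 were higher by 7.71, 6.46, 7.01 and 6.50. The isp-1 transcript itself was higher (0.21 ± 0.08, adjusted p = 0.0387, a call lost without any 1 library but wild-type control replicate 2) and aak-2 was not called (0.16 ± 0.08, adjusted p = 0.0914).

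Overall counts for isp-1 on control RNAi were 3985 higher and 3298 lower of 14856 genes by edgeR (2032 and 321 past a 2-fold change), and 3562 and 3638 by DESeq2. Total-count scaling moved the median of all genes by 0.195 and gave 1543 lower genes, so that 77.2% rather than 54.7% of called genes were higher.

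**Figure D3:**
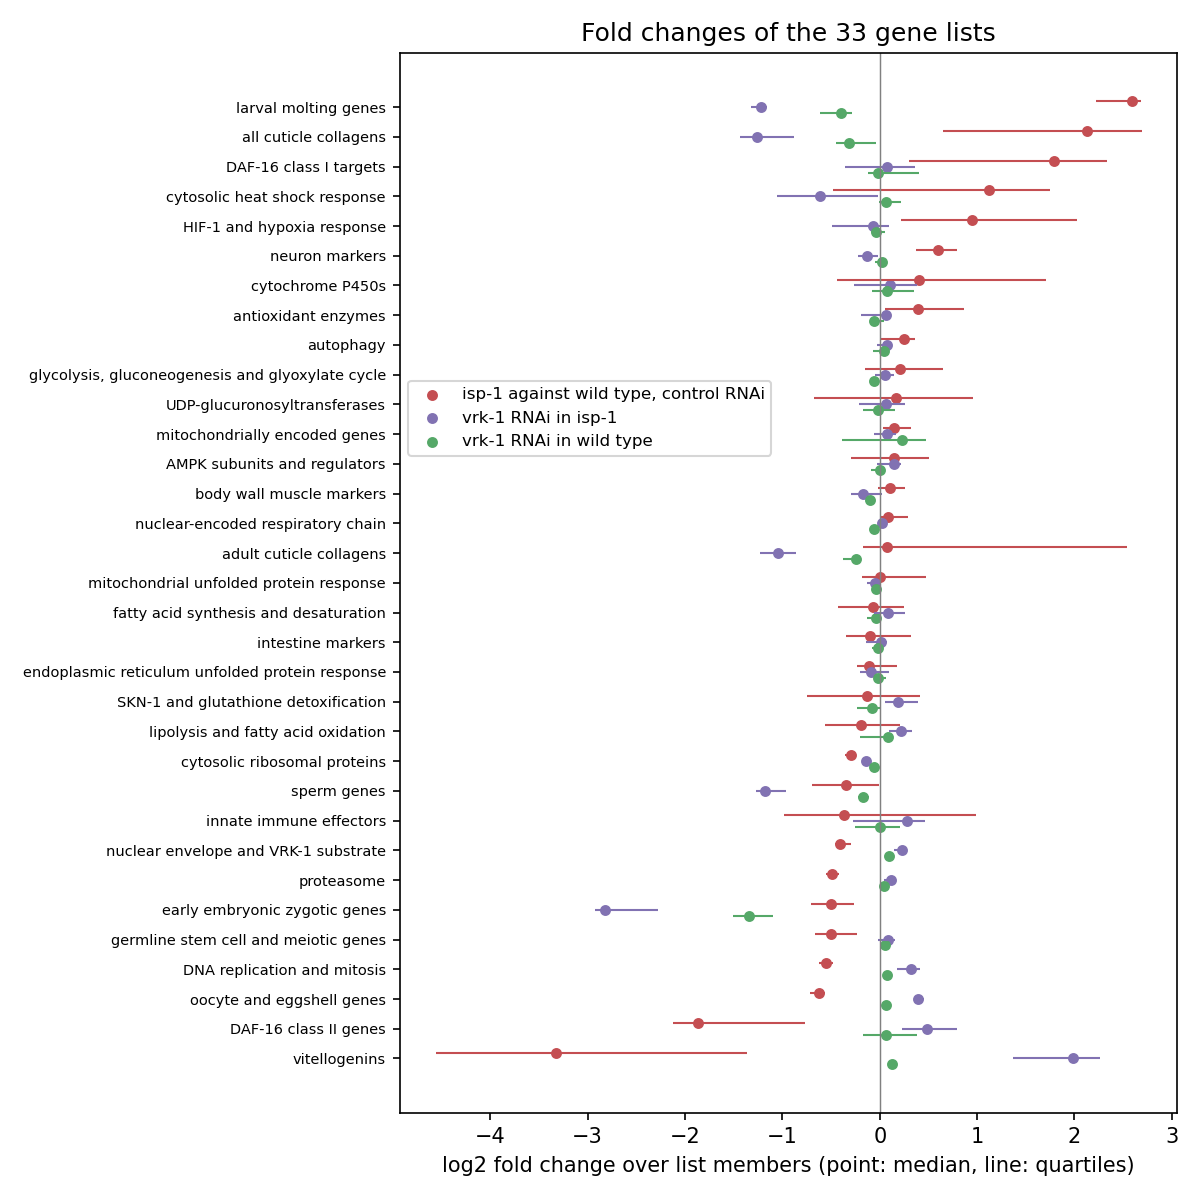
Median (point) and quartiles (line) of the log2 fold changes of the members of each of the 33 lists, for isp-1 against wild type on control RNAi (red), vrk-1 RNAi in isp-1 (purple) and vrk-1 RNAi in wild type (green). Vitellogenins stand at -3.32, 1.98 and 0.13, larval molting genes at 2.59, -1.22 and -0.40, and sperm genes at -0.35, -1.18 and -0.17.

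The isp-1 effect was measured again with both genotypes on vrk-1 RNAi. HIF-1 genes (8 of 12 higher, median 0.58; sqrd-1 2.97 ± 0.21), DAF-16 class I targets (10 higher and 1 lower of 13; sod-3 2.47 ± 0.18) and proteasome genes (31 of 33 lower, median -0.44) kept their direction. Vitellogenins were lower for 4 of 6 members (median -1.48; vit-3 -3.87 ± 0.28), molting genes higher for 15 of 17 (median 1.72) and collagens for 68 of 156 with 6 lower. Sperm genes were lower for 16 of 19 (median -1.37; msp-10 -1.34 ± 0.18), and DNA replication and oocyte genes for 14 of 23 and 6 of 17. By camera the adjusted p of these 9 lists lay between 5.96e-09 and 0.0401. The 0.0401 is that of oocyte genes, whose call ended with the block within each genotype (adjusted p = 0.0723). With an estimated correlation the adjusted p was 0.114 for HIF-1, 0.0711 for DAF-16 class I, 0.435 for proteasome and molting genes, 0.297 for vitellogenins and sperm genes, 0.665 for replication genes and collagens and 0.775 for oocyte genes. Camera called 8 more lists in the direction they had on control RNAi: DAF-16 class II, ribosomal and germline genes (3 of 5, 74 of 81 and 15 of 20 lower), and antioxidant, glycolysis, autophagy, cytochrome P450 and neuron genes (8 of 15, 13 of 21, 7 of 15, 26 of 59 and 8 of 17 higher). Their adjusted p lay between 6.53e-13 and 0.00942, and adjusted p between 0.0815 and 0.477 with an estimated correlation. Several counts rest on single libraries. Without wild-type vrk-1 RNAi replicate 1 or 3 or isp-1 vrk-1 RNAi replicate 1 or 2, the replication genes lower were 8, 7, 7 and 6 and the oocyte genes 2, 2, 2 and 1, and without isp-1 vrk-1 RNAi replicate 3 the oocyte genes were 14. The collagens higher were 36, 38 and 37 without wild-type vrk-1 RNAi replicates 1 and 3 and isp-1 vrk-1 RNAi replicate 2. Germline genes lower were 8 without isp-1 vrk-1 RNAi replicate 1 or 2, and autophagy genes higher 4 without wild-type vrk-1 RNAi replicate 1.

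With vrk-1 RNAi in both genotypes, aak-2 was higher in isp-1 (0.46 ± 0.08, adjusted p = 0.00037) and so was isp-1 itself (0.25 ± 0.08, adjusted p = 0.0208, a call lost without wild-type vrk-1 RNAi replicate 1 or isp-1 vrk-1 RNAi replicate 2), while vrk-1 was not called (-0.10 ± 0.40). Among the largest changes, lsy-27, F47H4.2 and C18D4.6 were 434.5-fold, 267.1-fold and 189.7-fold higher in isp-1 against the wild-type floor. The gene argk-1 was at least 622.5-fold lower. The argk-1 bound rests on wild-type vrk-1 RNAi replicate 2 (75.3 CPM) and is 134.1-fold without it. The argk-1 call was lost without any 1 of the isp-1 vrk-1 RNAi libraries. The 3 higher genes lie in the run without wild-type counts named above. F22B3.7 and F56A4.3 were higher by 8.67 ± 0.37 and 6.70 ± 0.28, and pud-3, pud-4, pud-1.2 and pud-2.2 (WBGene00017490) lower by -10.29, -9.24, -8.21 and -7.79. The counts were 3515 higher and 3103 lower by edgeR (1480 and 906 past a 2-fold change) and 3175 and 3239 by DESeq2. Total-count scaling gave 65.9% rather than 53.1% of called genes as higher.

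The interaction tests whether the log2 change with vrk-1 RNAi differed between isp-1 and wild type. It does not show what the mutant needs vrk-1 for, since the starting levels of many genes also differed between the genotypes. The interaction was called for 26 genes. The change was more positive in isp-1 than in wild type for 25. It was more negative for 1, the carboxykinase gene pck-3 (-1.42 ± 0.26). A positive interaction need not be a larger response in isp-1. The gene folt-2 changed by -0.79 in wild type and 0.13 in isp-1, and hphd-1 by -0.63 and 0.39. Vitellogenin genes were 3 of the 26: vit-5 changed by 1.92 in isp-1 and 0.18 in wild type (interaction 1.74 ± 0.23, adjusted p = 0.0162), vit-3 by 2.56 and 0.14 (2.42 ± 0.36, adjusted p = 0.042) and vit-1 by 2.05 and 0.12 (1.93 ± 0.30, adjusted p = 0.041). F41G4.7 (3.04 ± 0.49, adjusted p = 0.0396) and W04A4.2 (1.56 ± 0.25, adjusted p = 0.0396) were also called. The detoxification gene gst-4 rose in isp-1 (0.85) with a value of -0.22 in wild type (1.07 ± 0.20, adjusted p = 0.0481), and ech-6 rose in isp-1 (0.45) with -0.41 in wild type (0.86 ± 0.15, adjusted p = 0.041). Also among the 26, and named after their values were seen, were the peroxisomal acyl-CoA oxidase gene acox-1.4 (0.89), the propionate shunt gene hphd-1 (1.02) and the cathepsin L gene cpl-1 (0.71). The interaction was not called for vrk-1 (0.16 ± 0.56), isp-1 (0.04 ± 0.11) or aak-2 (0.29 ± 0.11, adjusted p = 0.228).

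Of the lists, camera called 13 for the interaction, among them vitellogenins (3 of 6 members called, 6 adjusted over the list alone; median 1.84, adjusted p = 5.29e-25; adjusted p = 0.0501 with an estimated correlation). Sperm genes had 0 of 19 called and 15 lower adjusted over the list alone (median -0.99, adjusted p = 7.5e-11; adjusted p = 0.397 with an estimated correlation). Oocyte genes had a median of 0.34 (adjusted p = 1.65e-06; adjusted p = 0.622 with an estimated correlation) and replication genes of 0.22 (adjusted p = 3.66e-05; adjusted p = 0.727 with an estimated correlation), with no member called over all genes. The oocyte median was 0.22 without isp-1 control replicate 2 and 0.15 without isp-1 vrk-1 RNAi replicate 3. With the replicate block 6 vitellogenins, 2 oocyte and 2 replication genes were higher, 3 sperm genes lower, and 1 collagen higher and 6 lower. The fatty acid synthesis list, called without the block (adjusted p = 0.0396; adjusted p = 0.354 with an estimated correlation), was not called with it (adjusted p = 0.0678). The block within each genotype called the adult cuticle collagens (adjusted p = 0.000311, 0.234 without a block; adjusted p = 0.817 with an estimated correlation). SKN-1, lipolysis and cytochrome P450 genes then had 2 higher each, UDP-glucuronosyltransferases 2 higher and 3 lower, innate immune effectors and intestine markers 1 higher each, and heat shock and ribosomal genes 1 lower each. The number of genes called moved with the setting: 194 higher and 457 lower with the replicate block, 147 and 234 by DESeq2 and 0 with total counts. It fell to 0 without wild-type control replicate 1 or 3, and to 2 higher without wild-type control replicate 2. It was 5 higher and 1 lower without wild-type vrk-1 RNAi replicate 1, 6 and 4 higher without isp-1 control replicates 1 and 2, and 1 higher without isp-1 vrk-1 RNAi replicate 1. It was 105 higher and 359 lower without isp-1 vrk-1 RNAi replicate 2 and 72 higher without replicate 3.

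Across the genes tested, the changes with vrk-1 RNAi in wild type and in isp-1 correlated (Pearson r = 0.417, Spearman rho = 0.421), with the same sign for 66.7% of genes; genes are not independent replicates. Simulated unchanged groups gave r = -0.002. Their genes were drawn independently, without the variation that genes of a real library share, so this value does not bound r by chance. Of the 2923 genes called in isp-1, 83.2% had the same sign in wild type, with a median log2 change of 0.127 in that direction against 0.992 in isp-1, and 0 were called in both. Without wild-type vrk-1 RNAi replicate 2, r was 0.592 and 65 genes were called in the same direction in both. Without both replicate 2 libraries the medians were 0.196 in wild type against 0.806 in isp-1, over 4720 genes called in isp-1. Each time the genes were chosen by their change in isp-1, which by itself enlarges that change relative to the one in wild type. How much of either gap this choice makes was not measured. Over all libraries no gene was called in wild type, so the reverse choice could not be made.

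The isp-1 effects on control and on vrk-1 RNAi correlated across genes at r = 0.835 (rho = 0.783). Of the 7283 genes called on control RNAi, 65.3% were called in the same direction on vrk-1 RNAi: 2752 higher, where independence gives 942.9, and 2006 lower, where it gives 688.9. The same sign held for 96.8%, with a median of 0.505 on vrk-1 RNAi against 0.655 on control RNAi. Of the genes chosen on vrk-1 RNAi, 71.9% were called the same way on control RNAi. Their median was 0.539 on control RNAi against 0.728 on vrk-1 RNAi. Choosing genes in 1 contrast shrinks their change in the other by chance, so neither gap alone shows a weaker isp-1 effect. By the mean of the 2 absolute changes, the top 5 genes called in both, with at least 5 CPM and a symbol, were argk-1, pud-3 and pud-4, lower in isp-1, and lsy-27 and F47H4.2, higher.

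Genes changed by the mutation and moved back by vrk-1 RNAi numbered 1302: 677 were higher in isp-1 and lowered by vrk-1 RNAi (491.4 by independence), and 625 were lower in isp-1 and raised (242.2). Only 54 and 65 moved further in the direction of the mutation, against 292.7 and 406.7. By the mean of the 2 absolute changes, the top 5 with at least 5 CPM and a symbol were vit-3 (-6.29, then 2.56), vit-4 (-4.77, then 2.33), clec-17 (6.46, then -0.49) and the collagen genes col-41 (5.24, then -1.61) and col-176 (4.62, then -1.54). The changes of clec-17, col-41 and col-176 with vrk-1 RNAi were each not called without isp-1 control replicate 2 or vrk-1 RNAi replicate 1, among others. These contrasts share the isp-1 control libraries, which by itself gives opposite signs: simulated unchanged groups had a covariance of -0.0369, against -0.2618 measured. Their r was -0.49 against -0.372 measured (rho = -0.467), but r also depends on the variance that real changes add, so the 2 values of r are not comparable. The simulated genes were again drawn independently, so variation shared by genes of an isp-1 control library is not in the -0.0369. With 1 isp-1 control library giving the isp-1 effect and the other 2 the change with vrk-1 RNAi, 65.9% to 67.2% of the genes tested had opposite signs. The count was 2404 with the replicate block, 256 without isp-1 control replicate 2, 315 and 577 without isp-1 vrk-1 RNAi replicates 1 and 3, and 2218 without replicate 2.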

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

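The tests of the 3 patterns, the counts of splits, and leaving out both replicate 2 libraries or the vitellogenin genes were chosen only after the data were seen, the last before its own result was, while the replicate block, DESeq2 and total counts were planned. The change with vrk-1 RNAi differed between isp-1 and wild type by the interaction term for 26 genes. It was more positive in isp-1 for 25 and more negative for 1. The interaction was 3.044 for F41G4.7, 2.419 for vit-3, 1.928 for vit-1, 1.743 for vit-5, 1.56 for W04A4.2 and -1.422 for pck-3, with adjusted p of 0.0396, 0.042, 0.041, 0.0162, 0.0396 and 0.0481. All 26 kept their call and direction with both vrk-1 RNAi replicate 2 libraries left out, with the replicate block and by DESeq2, but these settings called more genes lower than higher (82 higher and 179 lower, 194 and 457, and 147 and 234). With total counts 0 were called. Of the 26, 0 stayed called without wild-type control replicate 1 or 3, 2 without wild-type control replicate 2, 5, 12 and 16 without wild-type vrk-1 RNAi replicates 1, 2 and 3, 6, 4 and 15 without isp-1 control replicates 1, 2 and 3, and 1 without isp-1 vrk-1 RNAi replicate 1. Of 100 splits of the libraries for the interaction, 4 gave at least 26 genes, the real one included, and the highest of the others gave 3485, which points to a structure of the samples. The other 3 kept the 2 isp-1 groups whole and mixed wild-type libraries only, so they retain the effect of vrk-1 RNAi in isp-1. Of 8 such splits only these 3 reached 26 genes, so retaining that effect does not by itself give such counts. All 3 put wild-type control replicates 1 and 2 in 1 group with the isp-1 vrk-1 RNAi libraries. Of 91 splits that mixed the isp-1 groups 0 reached 26 genes. The 1st draw of 60 splits also held 4 with at least 26 genes, a share of 0.067, and the number was raised to 100 after that was seen, for a share of 0.04; with shares on both sides of 0.05, and splits that retain an isp-1 effect, chance is not claimed to be excluded.

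For the other contrasts the 6 libraries make 10 splits, too few for a share under 0.05. For vrk-1 RNAi in wild type, 10 of 10 splits called at least the real count of 0, and the highest other split called 1. Every split reaches a count of 0, so this share was fixed in advance and holds no information on chance. For vrk-1 RNAi in isp-1, isp-1 on control RNAi and isp-1 on vrk-1 RNAi, 1 of 10 splits, the real one, reached the real counts of 2923, 7283 and 6618, and the highest other split called 0 in each. All these splits, and those for the interaction, treat libraries as exchangeable, although same-numbered libraries deviated together within each genotype. For vrk-1 RNAi, some splits part all 3 same-numbered pairs, as the real one does, and the rest part only 1.

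The 1st pattern weighed is the control-like level of vrk-1 in both libraries labelled vrk-1 RNAi replicate 2. A swap with a control library of the same genotype would leave a control library with low vrk-1, but the lowest control level was 86.15 CPM against 56.68 CPM for the highest of vrk-1 RNAi replicates 1 and 3, which argues against it. On an axis from control (0) to vrk-1 RNAi replicates 1 and 3 (1) built without vrk-1, wild-type replicate 2 lay at -0.004, with the highest control at 0.359, as animals without an RNAi response would; a wrong label from outside the series stays open and could give the same value. The isp-1 replicate 2 lay at 0.555 against 0.235 for the highest control, so it differed from the controls along this axis. The axis does not separate a response to vrk-1 RNAi from other differences between libraries, such as timing at harvest. Animals without a response therefore stay open for it. No biological explanation was tested.

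The 2nd pattern is the rise of vitellogenin and oocyte genes and the fall of sperm and molting genes with vrk-1 RNAi in isp-1. Vitellogenin reads displacing other counts would end the falls once those genes are left out, but 27 of the 27 sperm and molting genes called lower stayed called. TMM scaling already limits such displacement, so this test could hardly have come out otherwise. Vitellogenins held 2.6% to 3.6% of counts in isp-1 on control RNAi and 5.8% to 8.2% on vrk-1 RNAi. Most counts thus lay outside these genes in both groups, which argues against displacement as the source of the falls. For the vitellogenin, oocyte and molting genes a shift of the mutant toward the wild-type profile cannot be told apart from other causes: 97.5% (39 of 40) moved toward the wild-type level, with 1 isp-1 control library giving the distance from wild type and the other 2 the change, but these lists were chosen after both changes were seen, so the share restates the pattern. A shift is argued against for sperm genes, whose median in isp-1 on vrk-1 RNAi was -1.5 from wild type on control RNAi, further away than the -0.35 of isp-1 on control RNAi, with 19 of 19 members negative. A difference in age or developmental timing at harvest between the libraries may contribute, and these libraries hold no series of ages to test it.

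The 3rd pattern, noticed in the data, is a low level of fbxb genes with vrk-1 RNAi in both genotypes: the median of 47 members was -1.24 in wild type with 0 called and -3.38 in isp-1 with 25 lower and 1 higher (-3.07 with members without counts in a group at their bound), at a median level of 0.451 CPM. The count of 0 and the gap between the genotypes rest on the library labelled wild-type vrk-1 RNAi replicate 2: without it the wild-type median was -4.57 with 16 lower, and without both replicate 2 libraries -4.57 with 19 lower in wild type and -3.25 with 33 lower in isp-1, whereas the wild-type median was -0.77 without vrk-1 RNAi replicate 1 and -0.80 without control replicate 3; the isp-1 count also fell to 12 and 9 without isp-1 control replicates 1 and 2 and to 7 and 8 without isp-1 vrk-1 RNAi replicates 1 and 3. The camera adjusted p was 1.7e-29 and 7.82e-11, and with an estimated correlation the adjusted p was 0.903 and 0.838. Reads shared between near-identical copies, which would leave unrelated genes alone, and fewer embryos with active transcription in the animals, which would lower them, cannot be told apart: 20 sdz and early embryonic genes had a median of -1.36 in isp-1, with 16 negative but only 5 called lower and 2 higher (-0.85 for the 18 sdz genes alone), and of -1.09 in wild type, with 18 negative and 0 called, while oocyte genes had 0.06 in wild type. The wild-type median of the 20 was -2.09 with 9 called lower without vrk-1 RNAi replicate 2 and -0.76 with 12 negative without control replicate 3, and the bar for deciding, 1 of 2 members called, was set after these values were seen. In isp-1 the number called lower was 10 without both replicate 2 libraries, which reaches that bar. It was 9 (median -2.36) with the 6 libraries alone. It was 2 or 3 without isp-1 control replicate 1 or 2 or vrk-1 RNAi replicate 1 or 3.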

How the results depend on the processing

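The block within each genotype, leaving out both vrk-1 RNAi replicate 2 libraries and leaving out the vitellogenin genes were chosen only after the data were seen, the last before its own result was. The counts and percentages named here moved by over 1.5 times or by more than their spread, and the cause was not tested except where given. A 2-fold minimum is stricter by construction, and leaving out libraries lowers the number of samples.

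For vrk-1 RNAi in wild type, where edgeR called 0 genes (504 at an unadjusted p under 0.05), no count filter gave 2 lower, the block within genotype 2, the 6 libraries alone 1, DESeq2 6, and leaving out both replicate 2 libraries 21 higher and 178 lower. For vrk-1 RNAi in isp-1, the number higher was 588 with total counts, 1742 with the replicate block, 2120 with the block within genotype, 616 with the 6 libraries alone, 1978 without both replicate 2 libraries and 96 at a 2-fold minimum, and the number lower was 2891 with the block within genotype. For isp-1 on control RNAi, a 2-fold minimum gave 2032 higher and 321 lower and total counts 1543 lower. For isp-1 on vrk-1 RNAi, a 2-fold minimum gave 1480 and 906.

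For the interaction, the number higher was 0 with total counts, 194 with the replicate block, 406 with the block within genotype, 82 without both replicate 2 libraries, 147 by DESeq2 and 13 at a 2-fold minimum. The number lower was 0, 457, 1025, 179 and 234 for the first 5 of these, and 5 with no count filter. Genes called in both genotypes with vrk-1 RNAi numbered 1 with the block within genotype, 1 by DESeq2 and 124 without both replicate 2 libraries. Pearson r across genes was 0.183 with no count filter and 0.565 without both replicate 2 libraries. The share of isp-1 effects called again on vrk-1 RNAi was 48.4% without both replicate 2 libraries. Genes moved back by vrk-1 RNAi numbered 2404 with the replicate block, 2158 with the block within genotype, 2645 without both replicate 2 libraries and 417 at a 2-fold minimum. The 2158 rests on an isp-1 effect at the fitted level of replicate 1 only.

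Leaving out each library in turn gave 0 to 20 genes higher and 0 to 165 lower for vrk-1 RNAi in wild type, the highest without wild-type vrk-1 RNAi replicate 2. It gave 315 to 1910 and 673 to 2393 for vrk-1 RNAi in isp-1, 3115 to 3713 and 2390 to 3552 for isp-1 on control RNAi, 2636 to 3871 and 2367 to 3433 for isp-1 on vrk-1 RNAi, and 0 to 105 and 0 to 359 for the interaction. The overlap ranged from 0 to 65, r from 0.234 to 0.592, the share called again from 49.8% to 76.1% and the genes moved back from 256 to 2218.

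Of the results for named genes that were called, 5165 comparisons with an alternative kept call and direction and 387 lost the call, and of those not called 1299 stayed so, 85 became called and 15 changed sign. These sums hide a difference between comparisons: with 1 library left out, calls of named genes were lost in 171 of 558 cases for vrk-1 RNAi in isp-1 and 62 of 96 for the interaction, against 24 of 840 for isp-1 on control RNAi and 21 of 768 on vrk-1 RNAi. For lists, 759 kept the call, 195 lost it, 1155 stayed uncalled and 69 became called. The 15 sign changes were all of values not called. For vrk-1 in isp-1 against wild type on vrk-1 RNAi they were 0.02 with total counts, 0.22 with the block within genotype, 0.51 without wild-type vrk-1 RNAi replicate 2, 0.13 without isp-1 vrk-1 RNAi replicate 3 and 0.16 without both replicate 2 libraries, and its lowest value was -0.45 without isp-1 vrk-1 RNAi replicate 2. For the interaction of vrk-1 they were -0.07 without wild-type vrk-1 RNAi replicate 1, -0.07 without replicate 3 and -0.19 without isp-1 vrk-1 RNAi replicate 2, and the highest value was 0.78 without wild-type vrk-1 RNAi replicate 2. For the interaction of isp-1 they were -0.05 with total counts and -0.01 without wild-type control replicate 2, up to 0.10 without replicate 3. For vet-6 they were 0.05 with the block within genotype for isp-1 on control RNAi, and 0.39 without wild-type vrk-1 RNAi replicate 2 and 0.54 without both replicate 2 libraries for isp-1 on vrk-1 RNAi, where the lowest was -2.59 without wild-type vrk-1 RNAi replicate 3. For the interaction of sdz-28 they were 1.36 and 1.38 in the same 2 settings, and the lowest was -2.1 without wild-type vrk-1 RNAi replicate 1. The sign changes of vrk-1 and vet-6 with the block within genotype compare the fitted levels of replicate 1 only. They do not show an effect of adjusting for replicate. Depth limits the low-level genes most, since a gene at the floor of 3 counts per group gives only a bound.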

Other observations

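The families below were chosen after their values were seen, from 136 families of at least 10 genes with the same name stem. On control RNAi, neuropeptide genes were higher in isp-1: 28 of 30 flp genes (median log2 change 1.00, camera adjusted p = 6.56e-10), 33 of 48 nlp genes with 1 lower (0.93, adjusted p = 1.52e-06) and 15 of 23 insulin-like ins genes with 1 lower (1.05, adjusted p = 0.00496). Nuclear hormone receptor nhr genes had 95 higher and 9 lower of 182 (0.56, adjusted p = 6.04e-06) and pals genes 14 higher and 1 lower of 21 (1.02, adjusted p = 0.00051). Translation initiation eif genes were lower for 21 of 25 (-0.45, adjusted p = 3.23e-08) and nuclear pore npp genes for 23 of 26 (-0.41, adjusted p = 2.27e-05). With vrk-1 RNAi in isp-1, 26 of 29 msp genes (-1.14, adjusted p = 2.93e-19) and 17 of 26 spe genes (-1.13, adjusted p = 1.67e-07) were lower. With an estimated correlation the adjusted p was 0.791 for each family of the genotype contrast and 0.838 for msp and spe, and all these medians kept their direction under total counts.

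On chromosome V, 43 consecutive protein-coding genes from srg-44 to fbxa-176 (V:17328797-17551209) had 0 counts in all 6 wild-type libraries. In the isp-1 libraries 22 of them had counts, 17 of these over 10, with 9093 counts in total. The 10 that were tested were called higher in isp-1 on both bacteria, among them lsy-27, F47H4.2 and C18D4.6 at 19.1, 15.7 and 8.76 CPM over the isp-1 libraries. The neighbouring genes sdz-16 and C38D9.8 had 38 and 21 counts in wild type and 35 and 16 in isp-1. On the same chromosome argk-1 (V:16103894-16105952) had 0 counts in all 6 isp-1 libraries and a mean of 43.9 CPM in wild type.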
